A study of Oryza sativa with 2 samples.

How the data were processed

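Small RNA was prepared from rice spikelets of the cultivar Mahalaxmi, collected at day 6 after fertilization from the apical and the basal part of the panicle. Per the labels' protocols, total RNA that passed an integrity minimum was enriched for small RNA and given barcoded adapters with an Ion Total-Seq kit. The libraries were then pooled and sequenced on an Ion Proton instrument. Each position has 1 library. The sample labels gave the group of each library.

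Each deposited table is the result table of miRDeep2, a program that scores hairpin loci from mapped small RNA reads, per the file headers. It has 4 parts: a survey of performance by score, predicted miRNAs outside miRBase (the public miRNA database), miRBase miRNAs that the program detected, and miRBase precursors that it did not detect. The read counts in these parts are raw, not normalized counts of reads on the mature, loop and star (opposite-arm) stretches of each hairpin, per the file headers. The score of each locus and its estimated probability of being a true positive are the authors' deposited values from the same program. The aligner settings, program version, genome build and miRBase release are not given in the sources used here. The total number of reads per library is also not given in the sources used here. Coordinates are those of the tables, written from 1. 6 lines in each table were empty and were not analysed here.

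The tables list several precursors or loci for many mature sequences. Listed loci and precursors that share a mature sequence, letter for letter, were joined into 1 known miRNA, which takes the reads of its most abundant member. This gave 367 known miRNAs in 273 families. A name beginning with MIR marks a miRNA counted in the part on undetected precursors, where the mature sequences of a precursor share 1 count if it lists several. In the part on undetected precursors, a read is counted once for each listing of the same sequence. All 29 such precursors with reads in the apical table, and all 30 in the basal table, had counts divisible by the number of listings, against 11.2 and 11.6 expected by chance. The whole count of each undetected precursor was therefore divided by the largest number of listed sequences on 1 arm. Sequences were on the same arm when they overlapped by at least 10 nt, whether identical or not. The divisibility check covered only precursors that list 1 sequence repeatedly, so for other precursors the division is an assumption. Of the 367 miRNAs, 306 were counted in the same entry of both tables, 14 in different entries, and 47 were listed in 1 table only. Sequences that differ at few positions can share reads, so a family sum can count a read more than once.

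Values were scaled to reads per 1000000 known mature reads. The ratio is the log2 of basal over apical, with an exact conditional binomial (Clopper-Pearson) 95% interval. A miRNA or family was past the size rule when it had at least 50 reads over both libraries and its whole interval lay above 1 or below -1. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. The floor of 3 reads equals 7.56 reads per 1000000 in the apical library and 7.34 in the basal library. No test across samples was possible, and none was made. The lists of families were fixed before the data were examined. A list's median over families with at least 10 reads was placed among 10000 random lists of the same size, each member drawn from the 20 families nearest in reads, and its counting interval came from 2000 Poisson resamples. Predicted loci were shared when they overlapped on the same strand by at least 50% of the shorter hairpin.

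Named miRNAs followed a rule fixed beforehand. It took the 5 known miRNAs with most reads in each library, and up to 10 per direction with the largest ratio past the size rule. It also allowed families of the fixed lists with at least 10 reads over both libraries. Among predicted loci it took the 5 with the highest score in each library and the 5 shared loci with most reads.

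The alternatives were scaling by the median of ratios, by the trimmed mean of M values (TMM, from edgeR 4.0.16 in R 4.3.3), by the total without the most abundant miRNA and by the total of known and predicted reads. Others were the mean or the sum over precursors, read minimums of 10, 200 or none, thinning of the deeper library, stricter scores and other overlaps. Alternatives chosen after the data were seen left out miRNAs counted in different parts of the tables or over 2 arms, took only the most abundant sequence of each family, or added the unlisted MIR529a reads to the total. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

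The ratio and its interval were tested on simulated data, with counts drawn for the 367 miRNAs at the real depths and 200 of them changed in each of 50 runs. The 95% interval covered the true basal over apical ratio in 95.3% of cases. The simulated counts had Poisson error only and were scaled by the depths they were drawn with. Coverage near 95% was thus built in, and error from scaling or from PCR was not tested. The size rule took 0.0% of unchanged miRNAs, 2.4% of those changed 2-fold and 91.4% of those changed 4-fold.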

Results

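Small RNAs were sequenced from developing rice spikelets, the flower units that each fill into a grain, at day 6 after fertilization. Spikelets came from the apical and the basal part of the panicle, and the labels state the aim as identifying known and predicted miRNAs at both positions. Each position had 1 library and no replicates, so every difference below is one between these libraries and carries counting error only. The apical library had 396878 reads on known mature miRNAs and the basal library had 408935, so that 1 read equals 2.52 and 2.45 reads per 1000000. At least 1 read was found for 258 known miRNAs in the apical library and 265 in the basal library, of which 228 were found in both. The 30 miRNAs with reads only in the apical library had at most 9 reads each, and the 37 only in the basal library at most 22.

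Both libraries were dominated by miR396, the family that targets growth-regulating factors. The MIR396e group alone took 53.1% of known mature reads in the apical library (exact 95% interval 52.95 to 53.26) and 47.4% in the basal library (47.27 to 47.58). Next in the apical library was the sequence uuuggauugaagggagcucug, listed under the name miR159a.2, with 53429 reads. It belongs to miR159, the family that targets GAMYB transcription factors. MIR396b followed with 26659 reads, then miR535-5p with 14255 and the MIR167h group with 8801. In the basal library the same miRNAs led with 45693 reads for miR159a.2, 26266 for miR535-5p, 17340 for MIR396b and 13023 for the MIR167h group. The MIR396e group had 210755 apical and 193940 basal reads. By the deposited scores, the best locus of this group stood at -8.4 in both libraries, and that of miR159a.2 at -5.6. Known miRNAs whose best locus scored below 0 took 70.5% of apical and 63.5% of basal known reads. Those at 0 or more took 14.2% and 22.1%, and those without a detected locus 15.3% and 14.4%. The 5 most abundant miRNAs together took 79.1% of apical (78.97 to 79.22) and 72.4% of basal reads (72.31 to 72.58). The 10 most abundant took 86.5% (86.42 to 86.63) and 83.8% (83.73 to 83.95). Known miRNAs of 21 nt made up 86.0% of apical reads (85.92 to 86.13) and 86.2% of basal reads (86.07 to 86.29), and those of 24 nt 0.79% (0.77 to 0.82) and 0.92% (0.89 to 0.95).

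The comparison of apical with basal spikelets asked which known miRNAs differed by position. Past the 2-fold size rule were 5 miRNAs, all higher in the basal library. A miRNA counted over 2 arms entered as 1 joint count, so a single arm past the rule could be missed. miR528-5p, which targets copper proteins such as ascorbate oxidase, had 1954 apical and 5589 basal reads, a log2 ratio of 1.47 (1.40 to 1.55). Its sequence is uggaaggggcaugcagaggag, from a hairpin on the plus strand of chromosome 3 (1667331 to 1667416). miR1425-5p, a rice miRNA that targets pentatricopeptide repeat genes (uaggauucaauccuugcugcu, chromosome 5, 8862163 to 8862240, plus strand), had 2148 and 5409 reads, a log2 ratio of 1.29 (1.22 to 1.36). The sequence listed for MIR529a (cuguacccucucucuucuuc) had 157 and 460 reads, a log2 ratio of 1.51 (1.24 to 1.78). miR1846e had 33 and 105 reads, a log2 ratio of 1.63 (1.05 to 2.24). MIR2118o had 6 and 45 reads, with the largest log2 ratio of the 5 at 2.86 and the widest interval (1.63 to 4.38). Among families, miR528, miR1425 and miR1846 were past the rule, the last at 1.52 (1.01 to 2.05). Of these, miR528 stayed past it under the 5 other scalings. miR1425 was no longer past it with the median of ratios and TMM, and miR1846 was past it elsewhere only with the total of known and predicted reads. Under the other 4 scalings miR1850, a joint count over 2 arms, passed the rule in the apical direction. It ranged from -1.31 (-1.56 to -1.06) with the total with the unlisted MIR529a reads to -1.56 (-1.81 to -1.31) with the median of ratios.

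The 102 miRNAs with at least 50 reads had a median log2 ratio of 0.37, and the whole interval lay above 0 for 50, below 0 for 19 and across 0 for 33. Scaling by the median of ratios lowers every ratio by 0.37 (a shift of -0.37), TMM shifts it by -0.33, the total without the most abundant miRNA by -0.16 and the total with the unlisted MIR529a reads by -0.12. With the median of ratios, 31 miRNAs lay above 0 and 30 below, and 4 were past the size rule: miR528-5p and MIR2118o higher in the basal library, MIR1850 (-1.56) and MIR396b (-1.04) higher in the apical library. Both MIR1850 and MIR396b are joint counts over 2 arms, so neither call can be assigned to a single mature sequence. With TMM, 34 miRNAs lay above 0 and 29 below, and with the total without the most abundant miRNA 40 and 24.

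**Figure D1:**
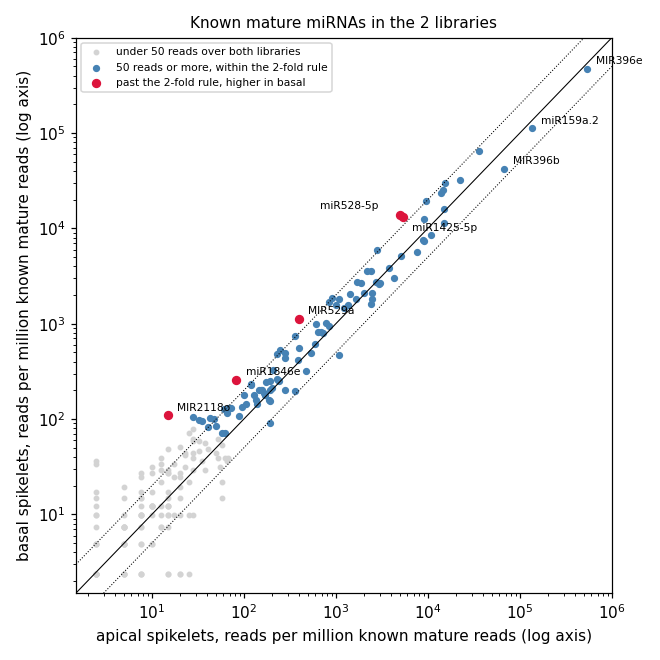
Known mature miRNAs with reads in both libraries, as reads per 1000000 known mature reads in the apical (x) and basal (y) library, both on log axes; each point is 1 miRNA, the solid line marks equality and the dotted lines a 2-fold difference. The 5 miRNAs past the 2-fold rule lie above the upper dotted line, and the MIR396e group stands at the top right.

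Families that target SPL transcription factors, regulators of panicle branching and phase change, were higher in the basal library. miR529 had 3992 apical and 8411 basal reads, a log2 ratio of 1.03 (0.98 to 1.09). miR156 followed at 0.95 (0.90 to 0.99) with 6157 and 12249 reads, and miR535 at 0.84 (0.81 to 0.87). miR172, which targets AP2-type genes downstream of the SPL factors, stood at 0.12 (0.00 to 0.23) with an interval that reached 0, and it turned below 0 with the median of ratios, TMM, the total without the most abundant miRNA and the total with the unlisted MIR529a reads. Of these 4 families, 3 thus had the whole interval above 0 and none below. The list's median was 0.89 (counting interval 0.87 to 0.92), at percentile 95.7 among random lists of like abundance, as a description of these libraries. The MIR529a precursor held a further 33029 apical and 73608 basal reads outside its listed sequence. The miR529 count above leaves these out. With them the family had 37021 and 82019 reads and stood at 1.10 (1.09 to 1.12), above 1 with the main scaling. Some of these reads may also be counted as miR529b. miR2118, fixed beforehand as a marker of anther tissue, was also higher in the basal library, at 0.81 (0.59 to 1.03).

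Families that target transcription factors of organ development split in direction, with 3 above 0 and 4 below. miR164, which targets NAC genes, was at 0.81 (0.77 to 0.85), and miR319, which targets TCP genes, at 0.62 (0.43 to 0.80). miR169, which targets NF-YA genes, was at 0.36 (0.28 to 0.43) and fell just below 0 with the median of ratios (-0.02). Of its 2628 apical and 3465 basal reads, 863 and 1472 came from miR169b, counted in different entries in the 2 libraries. The apical library was higher for miR396 at -0.22 (-0.22 to -0.21), miR159 at -0.26 (-0.28 to -0.25), miR166 at -0.30 (-0.34 to -0.26) and miR171 at -0.35 (-0.45 to -0.26), the last 2 of which target HD-ZIP III and GRAS genes. The median was -0.22 (counting interval -0.22 to -0.21), at percentile 2.8.

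Of the nutrient and copper families, 5 of 7 lay above 0, 1 below and 1 across 0. Besides miR528, the copper-responsive miR397 was at 0.83 (0.67 to 0.98), with miR398 at 1.03 (0.36 to 1.74) on 28 and 59 reads and miR408 at 1.06 (0.26 to 1.90) on 20 and 43 reads. The phosphate-responsive miR399 was at 0.19 (0.07 to 0.31) and turned below 0 with the median of ratios and TMM. Its members split in direction. MIR399d, with most reads, was at 0.51 (0.37 to 0.64), while MIR399c was at -0.57 (-0.90 to -0.24) and MIR399k at -0.89 (-1.30 to -0.49). miR827 was at 0.00 (-0.12 to 0.13), with no direction that held across scalings. The sulfate-responsive miR395 was higher in the apical library, at -1.04 (-1.64 to -0.46) on 76 and 38 reads, with its reads taken from different parts of the tables. The list's median was 0.83 (counting interval 0.29 to 0.95), at percentile 95.2, beside the 0.81 of the anther marker miR2118.

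Among auxin-related families, 3 lay above 0 and 1 below. miR160 and miR167, which target auxin response factors, were at 0.79 (0.68 to 0.91) and 0.43 (0.39 to 0.47). miR390, which triggers trans-acting siRNAs, was at 0.28 (0.10 to 0.45) and turned below 0 with the median of ratios and TMM. miR393, which targets auxin receptors, was at -0.17 (-0.29 to -0.05). That value is a joint count over 2 arms of MIR393b. The detected miR393a locus, joined to it and not used for the ratio, went the other way, with 154 apical and 259 basal mature reads. The median was 0.35 (counting interval 0.26 to 0.45), at percentile 57.5, and it turned to -0.02 with the median of ratios. For the miRNA machinery, miR162, which targets the Dicer gene, was at 0.48 (0.42 to 0.53). miR168, which targets the Argonaute gene, was at 0.10 (0.05 to 0.15) and turned below 0 with the median of ratios, TMM, the total without the most abundant miRNA and the total with the unlisted MIR529a reads. That pair had a median of 0.29 (counting interval 0.25 to 0.33), at percentile 40.1, which turned to -0.08 with the median of ratios and -0.04 with TMM. miR444, which targets MADS-box genes, was at -0.25 (-0.31 to -0.19), at percentile 17.4.

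miR2118, which triggers phased siRNAs in anthers, had 263 apical and 474 basal reads, at percentile 82.6. The other trigger family, miR2275, had 3 and 1 reads and was too rare to compare. Of the rice and monocot families, 12 of 15 were measured, with 5 above 0, 2 below and 5 across 0, a median of 0.44 (counting interval 0.26 to 0.78) and percentile 45.9. miR1432 was at 1.07 (0.35 to 1.83) and miR1861 at 0.90 (0.29 to 1.52). The apical library was higher for miR1850 at -1.18 (-1.44 to -0.94) and miR1874 at -0.44 (-0.58 to -0.30). Transposon-related families were scarce: 4 of 11 were measured, 1 of them, miR812 at 0.49 (0.24 to 0.74), above 0. Their median was 0.29 (counting interval 0.07 to 0.54), at percentile 39.1, and it turned below 0 with the median of ratios and TMM.

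**Figure D2:**
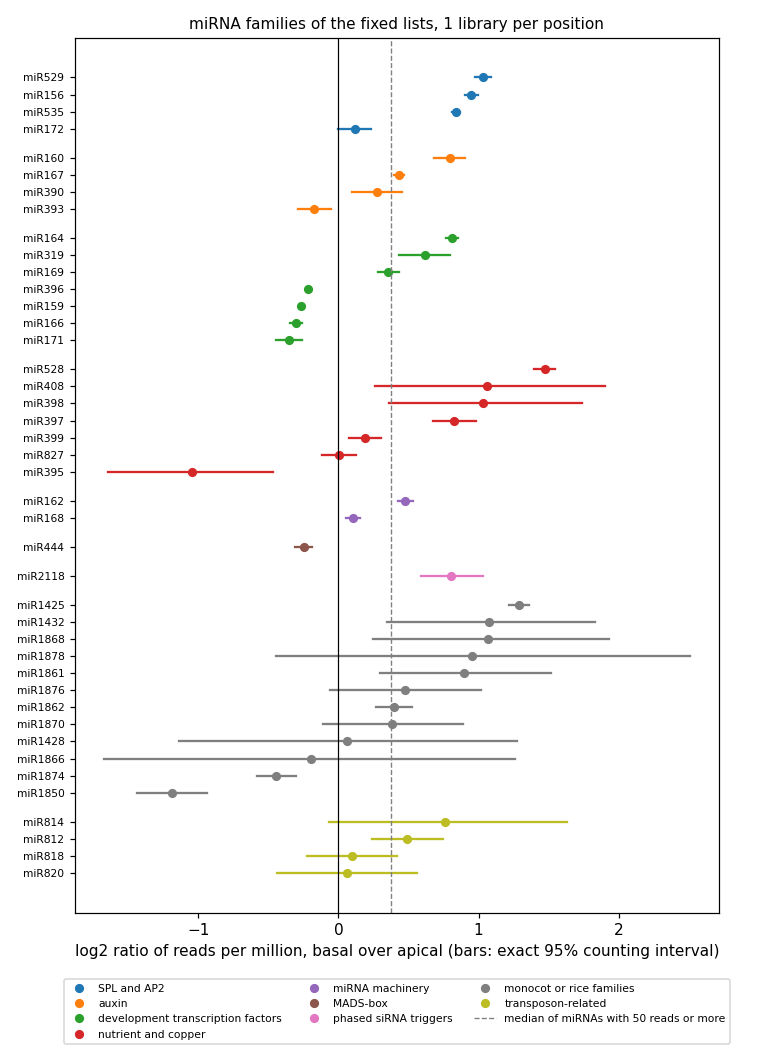
Log2 ratio of reads per 1000000, basal over apical, for families of the fixed lists with at least 10 reads; points are ratios, bars the exact 95% counting interval, colours the lists, and the dashed line the median of miRNAs with at least 50 reads (0.37). miR529, miR156 and miR535 lie to the right of the dashed line, while miR396, miR159, miR166 and miR171 lie to the left of 0; families between 0 and the dashed line, such as miR172, miR168 and miR399, turn below 0 with the median of ratios.

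The tables also list hairpins predicted outside miRBase, 64 in the apical and 90 in the basal library. By the authors' deposited estimate, 33% ± 10 of the apical and 21% ± 10 of the basal predictions at a score of 0 or more are true positives. The estimate changes with the score: at 2 or more it is 75% ± 9 and 75% ± 8, and at 10 or more 29% ± 26 and 20% ± 22, on 6 and 8 predictions. The libraries shared 26 of these loci, 20 of them with the same mature sequence. Of the shared loci, 16 had at least 50 reads, and none was past the 2-fold rule in either direction. A locus missing from a list had no listed score there, which does not show that it had no reads.

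The highest scores belonged to a pair of related hairpins found in both libraries. One lies on chromosome 10 (6928735 to 6928821, plus strand; uccgacccauacaagguuccgc), scored 400 apical and 350 basal, and had 447 and 418 mature reads. The other lies on chromosome 7 (13120590 to 13120676, minus strand), scored 310 and 250, and had 265 and 222 mature reads. Both list 351 apical and 280 basal star reads, equal counts that can be the same reads. Their log2 ratios were -0.14 (-0.34 to 0.06) and -0.30 (-0.56 to -0.04). Other shared loci with many reads were one on chromosome 11 (2523240 to 2523312, minus strand) opposite miR1862e, at 0.37 (0.19 to 0.56), and one on chromosome 6 (6769841 to 6769916, minus strand), at -0.34 (-0.57 to -0.11). The fifth shared locus by reads, on chromosome 7 (16674171 to 16674217), carries an rRNA alert. Listed in the apical library alone were loci on chromosome 8 (13935149 to 13935237), with 132 mature and 22 star reads, and chromosome 1 (40538937 to 40539028), with 16 mature reads. The latter shared its score of 11 with a 19-nt locus on chromosome 7 (22938396 to 22938483), also listed in the apical library alone, with 42 mature reads. A locus on chromosome 6 (13329856 to 13329922) scored 57 in the apical and 2.6 in the basal library, with 107 and 120 mature reads. Listed in the basal library alone were loci on chromosome 7 (13319078 to 13319138), chromosome 4 (9163647 to 9163693) and chromosome 9 (10629777 to 10629824), with 480, 415 and 102 mature reads of 17, 20 and 17 nt. The program's check of hairpin folding (randfold) was not significant for the loci on chromosomes 4 and 9. It was also not significant for the 19-nt apical locus on chromosome 7.

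Predicted loci were mostly of the 24-nt class, with 35 of 64 in the apical library (54.7%, interval 41.7 to 67.2) and 52 of 90 in the basal library (57.8%, 46.9 to 68.1). Another 20 and 23 loci had mature sequences of 20 to 22 nt. Loci shorter than 20 nt numbered 7 and 9, and they took 6.1% of predicted mature reads in the apical library (5.3 to 7.0) and 18.1% in the basal library (17.0 to 19.2). A single locus held 480 of these 903 basal reads and another 99 of the 194 apical reads, an rRNA-alert locus; without the largest locus of each library the shares were 3.1% (2.5 to 3.8) and 9.4% (8.5 to 10.3).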

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

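The tests in this part were all chosen after the results were seen. Read columns that the comparisons above do not use held signal above the 3 reads that a count of 0 allows. Star reads at the detected miRBase loci numbered 2260 in the apical and 2987 in the basal library. Precursors that the program did not detect held 49340 and 93250 reads outside their listed mature sequences.

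Most of those reads came from a single precursor. MIR529a held 33029 apical and 73608 basal reads outside its listed sequence, 66.9% and 78.9% of all such reads. Only 2 known miRNAs had more reads in the apical library, and 1 in the basal library. The log2 ratio was 1.11 (1.09 to 1.13). The next precursor, MIR444c, had 2030 and 2113.

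Several technical explanations for the MIR529a reads were tested. The reads were at least 8.61 times as many as those of miR529b, so miR529b reads counted again cannot supply most of them. The sequences of miRNAs with at least as many reads differed from every stretch of the precursor at 10 positions or more. The lower end of the interval stayed at 0.72 or above under 5 other scalings. This followed from the largest shift, -0.37, and cannot exclude a larger scaling error. The opposite arm of the hairpin (agaagagagagaguacagccu) differs from miR529b at 1 position and may be the source of these reads, in which case part of the miR529b count may be the same molecules. A difference between spikelet positions stays open and untested, because each position has 1 library.

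The higher basal level of miR156, miR529 and miR535 was weighed in the same way. If scaling set by the most abundant miRNA gave the whole difference, at least 1 of these families would reach 0 under another scaling. The lowest lower end over 5 other scalings was 0.44. This had to hold, because each scaling shifts all ratios alike and the largest shift was -0.37. It shows only that these 5 scalings do not remove the difference, and it cannot exclude a larger scaling error. Scaling still set part of the size. With the median of ratios, miR529 stood at 0.66, miR156 at 0.58 and miR535 at 0.47, against 1.03, 0.95 and 0.84. Reads shared between the families would need near-identical sequences, but the closest pair differed at 6 positions. A library difference that follows RNA length moves all miRNAs of a length alike under any scaling. The comparison took 39 other miRNAs counted on 1 arm, with at least 50 reads and 21 nt, the length of miR529b and miR535-5p. Of the 39, 24 had intervals wholly below 0.81, the smaller lower end of miR529b and miR535-5p, 4 wholly above and 11 across it. The 21-nt miRNAs thus did not all share 1 level. That a shift alike for all of them cannot by itself set miR529 and miR535 above the others holds by definition, whatever these counts. Because these families were picked after their values were seen, the comparison cannot tell whether length adds to their level. For miR156, of 20 nt, an effect of length cannot be told apart: all 3 other miRNAs of that length lay below its lower end (0.90), but 3 are too few to decide. What also remains open and untested is an effect of spikelet position, a different share of anther tissue (its marker miR2118 was also higher, at 0.81, 0.59 to 1.03), or a difference between individual libraries that affects some sequences more than others.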

How the results depend on the processing

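Every ratio here rests on 1 library per position, so no replicate could be left out. No paired analysis was possible because each position has 1 library and the shared number 1 is only a name. The scaling with the unlisted MIR529a reads was chosen after the data were seen, as were the alternatives without miRNAs counted in different parts or over 2 arms and with the most abundant sequence of each family only. Against 5 miRNAs past the size rule (5 basal, 0 apical) and 3 families (3 basal, 0 apical), the median of ratios gave 2 basal and 2 apical miRNAs and 1 family in each direction. TMM gave 3 miRNAs, 2 basal and 1 apical, and 1 family in each direction. The total without the most abundant miRNA and the total with the unlisted MIR529a reads each put 1 miRNA and 1 family, miR1850, past the rule in the apical direction. These counts move because a new scaling shifts all ratios alike. A minimum of 10 reads gave 9 miRNAs, all 9 basal, and 5 families, all 5 basal; no minimum gave 10 miRNAs, 9 basal and 1 apical, and 5 families, all 5 basal; a minimum of 200 reads gave 3 miRNAs, all 3 basal. Lists with a median above 0 fell from 7 of 9 to 4 with the median of ratios and 5 with TMM. At 10 reads or more, 128 apical and 146 basal miRNAs were detected, 122 in both. Summing over precursors, which counts reads repeatedly, raised the share of the most abundant miRNA to 70.2% and 63.3%. A score of at least 4 left 14 apical and 15 basal predicted loci with 3 shared, and a score of at least 10 left 6 and 8 with 2 shared. Of the alternative values for the main results, 58 were rated the same as the reported one, within 1.5-fold for counts, and 36 were rated as moved. Some of the 58 held clear losses: 2 families at a minimum of 200 reads, 49 apical loci with at least 10 mature reads and 20 shared loci with an identical mature sequence. Of the remaining values, such as list medians and ratios of named miRNAs, 79 were rated the same and 67 as moved. No named miRNA past the size rule changed direction under any scaling or way of combining precursors. Under the scalings this had to hold, since the lower ends lay above 1 and the largest shift was -0.37. Only miR528-5p and MIR2118o stayed past the rule under all 5 other scalings. miR1425-5p, MIR529a and miR1846e were lost with the median of ratios and TMM. miR1846e was also lost with the total without the most abundant miRNA and the total with the unlisted MIR529a reads. Depth limits the rarer miRNAs, whose intervals are wide, as for MIR2118o.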

Other observations

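The tests in this part were all chosen after the results were seen. Star reads gave a view of the opposite arm at 43 miRBase loci with at least 50 mature and star reads over both libraries, and the intervals of the 2 libraries lay apart at 9 of them, with the star share higher in the basal library at 3 and lower at 6. At miR394, which targets an F-box gene, star reads made up 10.6% of mature and star reads in the apical library (8.81 to 12.6) and 22.9% in the basal library (20.2 to 25.9), while the miR394 family itself was at -0.58 (-0.72 to -0.43). At a miR166 locus on chromosome 3 (30392799 to 30392861) the share was 1.48% (1.19 to 1.83) and 3.96% (3.41 to 4.57). It went the other way at miR535, with 4.01% (3.70 to 4.33) and 2.51% (2.33 to 2.71), at miR1425, with 4.24% (3.44 to 5.15) and 1.87% (1.53 to 2.26), and at miR1862d, with 45.0% (41.9 to 48.1) and 37.0% (34.3 to 39.6). It was also lower at 2 miR156 loci, on chromosome 2, with 1.68% (1.34 to 2.08) and 0.80% (0.64 to 0.99), and chromosome 4, with 1.14% (0.86 to 1.48) and 0.43% (0.31 to 0.58), and at miR1846e, with 13.2% (4.41 to 28.1) and 0 of 105 reads. At miR168 it was higher, with 1.10% (0.85 to 1.40) and 1.93% (1.61 to 2.28). These loci were chosen after their values were seen. The share also falls when mature reads rise, and all 6 loci with a lower share had more mature reads in the basal library. Raw star reads were higher there at miR535 (595 and 677), miR1425 (95 and 103) and miR1862d (465 and 490). They were not higher at the miR156 loci on chromosomes 2 (83 and 82) and 4 (56 and 44) or at miR1846e (5 and 0). The 2 miR156 loci list equal mature counts, 4844 apical and 10180 basal, which can be the same reads. The intervals overlapped at other miR156 loci with star reads. These were miR156f-5p (1.4% apical and 1.2% basal), miR156d (1.4% and 1.2%) and miR156a on chromosome 6 (0.8% and 0.9%).

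Families outside the fixed lists were also chosen after their values were seen. Of these, miR530 was higher in the basal library at 0.76 (0.72 to 0.81) on 5872 and 10273 reads. That count joins 2 arms, and the detected miR530-3p locus alone had 1278 apical and 2997 basal mature reads. The arms of miR530 were not put to the size rule separately. miR1873 was at 1.05 (0.76 to 1.35) and miR1320 at 1.06 (0.69 to 1.43).

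Predicted hairpins on the strand opposite a known locus numbered 3 in the apical and 4 in the basal library. Opposite miR1862e the antisense reads numbered 432 and 577, at least 151.1% of the sense reads, so misread sense reads cannot supply them. The antisense sequence differs from the star sequence of miR1862d at 1 position, and that star arm had 465 and 490 reads, so reads of the star arm of miR1862d may be counted here; whether they are cannot be told apart from a separate transcript, because the tables give no sequences of single reads. Opposite miR535 and a miR156 locus on chromosome 1 the antisense reads were at most 0.21% of the sense reads, and their sequences lay within 2 edits of the sense sequence. Misread sense reads may account for these loci, and a rare antisense transcript stays open. The remaining basal locus, opposite miR167, had 11 reads against 13005 sense reads, but its sequence lies 3 edits from the sense sequence, and its origin was not tested. No biological explanation was tested.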
